A study of Mus musculus with 9 samples.

How the data were processed

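Total RNA from 9 mouse pancreas tumours was analysed, 3 labelled KPC, 3 labelled KPC;TwistcKO and 3 labelled KPC;SnailcKO, here called KPC, Twist cKO and Snail cKO, each with a mouse number of its own in the labels and on its own array. The series' design text counts 2 mice per group, which the sources used here do not reconcile with the labels, and all 9 were used as labelled. Per the labels' protocols, the RNA was extracted with Trizol, checked on an Agilent Bioanalyser, made into biotin-labelled cRNA with the Ambion MessageAmp kit and hybridised to 1-colour Illumina mouse arrays. The submitters' processing notes name GenomeStudio 5.0 without saying what it was used for. The authors deposited a table with, per the file headers, an average bead intensity and a detection p-value for each of 45281 probes on each array. This intensity was linear and neither background-subtracted nor normalized between arrays, judging from its values. The detection p-value, per the file headers, ranks a probe against the array's negative controls. The authors also deposited a second table of processed intensity values. In it, each column was a straight-line function of that array's average bead intensity, with slopes of 0.795 to 1.16 and intercepts of -101 to -68.3. That table was therefore linear, with no centring by gene, and its direction followed the bead intensity. The method behind the subtraction and the scaling per array is not given in the sources used here. Its column medians were 14.6, 13.7 and 17.3 for KPC replicates 1, 2 and 3, then 21.7, 22.4 and 11.2 for the Twist cKO replicates, and 21.7, 23.3 and 9.3 for the Snail cKO replicates.

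Probes were named through the platform's annotation. A single gene symbol was given for 34885 probes, several for 18 and none for 10378, and only probes with 1 symbol were used. Of these, 34807 matched the RefSeq gene list of GRCm38.p6 by Entrez number, and 0 symbols needed an update. The files name no genome build, so no coordinates are printed and that list served only for names and for the order of neighbouring genes. Bead intensities were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, and the data.table package in version 1.17.8. The background mean and SD came from the detection p-values, and the offset was 16. Probes with a detection p-value under 0.05 on at least 3 of the 9 arrays were kept (20940, of which 17841 had a gene). Each gene was represented by its probe of highest mean intensity, which left 11524 of 19057 genes. More than 1 kept probe was available for 4359 genes, and disagreement between them is given where such a gene is named.

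A group-means model over all 9 arrays was fitted with lmFit and eBayes, so that the 3 groups shared 1 estimate of the spread. It left 6 residual degrees of freedom, to which the prior added 2.57, with a prior SD of 0.457. The comparisons were Twist cKO against KPC, Snail cKO against KPC, Snail cKO against Twist cKO, and the mean of both cKO groups against KPC. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of fold changes are standard errors from this fit, and errors of group means are SDs over 3 tumours. The p-values measure the spread between tumours labelled as separate mice, and the number of arrays limits the precision. Where a probe was above background on no array of a group, the ratio is a bound, the brighter group's mean against the higher of the probe's own signal and each array's lowest detected signal. Single values were also compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1.

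Lists of genes, 24 with 386 members in all, were fixed before the data were examined. They covered EMT transcription factors, epithelial and mesenchymal genes, nucleoside transport and gemcitabine metabolism, proliferation, fibroblasts, the TGF-beta pathway, hypoxia, the interferon response, handling stress, and markers of duct, mucinous, acinar, islet, T, B and plasma, macrophage, neutrophil, endothelial, adipocyte, smooth muscle, skeletal muscle, hepatocyte and erythroid cells. The 23 lists with at least 4 members tested were tested with fry, which asks whether the genes of a list move on balance one way. Its mixed p-value asks whether they move in either direction, and neither compares a list with other genes. The camera test, with a preset correlation of 0.01 and with an estimated correlation, was an alternative. The rule for named genes, fixed at the same time, took Twist1 and Snai1, then in each comparison the 5 genes of smallest unadjusted p in each direction where fewer than 5 passed, then up to 4 members of each list with the smallest p, and any member of the EMT and nucleoside lists. Predicted and clone names were counted but not named. Which of those list members serve as examples was chosen after their values were seen.

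The alternatives fixed in advance were no background correction, the deposited processed values, cyclic loess, median and spread scaling, no detection filter, a detection p-value under 0.01 on all 9 arrays, every probe tested on its own, an intensity trend, array weights, only the groups compared, the series of the sample title as a block, and leaving out each replicate in turn. Chosen after seeing the data were the array set as a block, each array set alone, and the fit without the KPC and the Twist cKO tumour that were low in epithelial genes. The steps were tested on simulated data, with 200 of 11524 genes changed by known folds over 10 runs of independent normal noise with each gene's own residual SD. At 4-fold, 47.8% of changed genes were recovered for Twist cKO against KPC, 50% for Snail cKO against KPC, 48.4% for Snail cKO against Twist cKO and 60.2% for both groups against KPC. At 2-fold the shares were 6.8%, 4%, 5% and 10.8% in the same order, and at 16-fold 85.4%, 86%, 85.2% and 88.2%. A list shifted by 1 on the log2 scale was called in 5, 5, 6 and 6 of the 10 runs. The noise was independent between genes, whereas camera estimated correlations of up to 0.945 within a list, so these list counts need not hold for the real data.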

Results

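Gene expression was measured in 9 whole pancreas tumours, labelled with 9 mouse numbers. KPC is the usual name for a strain of mice that develop ductal pancreatic cancer. The 3 KPC tumours had intact Twist and Snail, and the 3 Twist cKO and 3 Snail cKO tumours carried the KPC genotype as well, per their labels, and came, per the series' design text, from mice lacking expression of one of these factors in the pancreas. That text counts 2 mice per group while the labels give 3, and all 9 tumours were used as labelled. Twist1 and Snai1, the gene of Snail, encode transcription factors that repress epithelial genes and drive the epithelial-to-mesenchymal transition (EMT). A tumour piece also holds fibroblasts, vessels, immune cells and normal pancreas, so each value is a mean over all its cells. The arrays detected between 16707 probes (Snail cKO replicate 2) and 19606 probes (Twist cKO replicate 1), or 36.9% to 43.3% of all probes.

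The tumours differed widely in what they were made of, also within a group. KPC replicate 1 had a median of the epithelial junction and keratin genes 2.19 below the mean of the 9 arrays on the log2 scale (-2.19), and macrophage markers 1.86 above it. Twist cKO replicate 2 had epithelial genes at -2.16, duct cell markers at -3.95, and markers of B and plasma cells at 4.82, of T cells at 2.59 and of adipocytes at 5.40. Acinar cell markers, the digestive enzymes of the exocrine pancreas, were at 3.33 in Snail cKO replicate 3, which also had smooth muscle markers at 3.23, and between -1.84 and 1.76 in the other 8 tumours. Islet hormone genes were highest in KPC replicate 2 (2.27), and erythroid genes in Snail cKO replicate 1 (2.60). Across genes, the log2 intensities of pairs of tumours of the same group correlated with a median r of 0.895, and those of different groups with a median r of 0.909, over genes that are not independent replicates. Of the 143 single-gene differences recomputed without each tumour in turn, 76 shrank by more than 1.5 times or turned when 1 tumour was left out. The tumour that lowered them most was Twist cKO replicate 2 for 26 and KPC replicate 1 for 23.

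**Figure D1:**
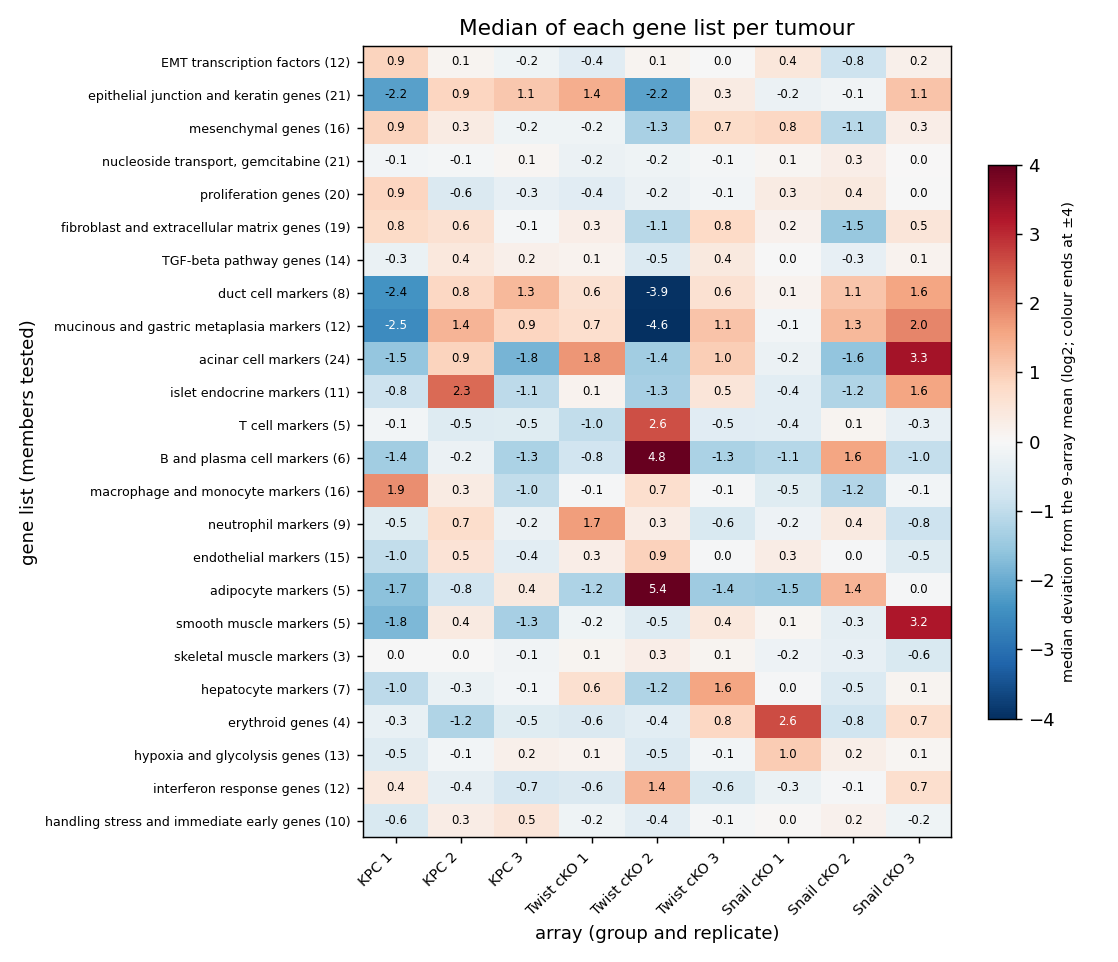
Each cell gives, for 1 gene list (vertical axis, with its number of tested members) and 1 tumour (horizontal axis), the median deviation of the list's genes from their mean over the 9 arrays, on the log2 scale. Twist cKO replicate 2 stands out with adipocyte markers at 5.40 and duct cell markers at -3.95, and Snail cKO replicate 3 with acinar cell markers at 3.33.

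The arrays also fell into 2 sets that the labels do not name. The median raw signal was 99.1 to 107.2 on the 3 KPC arrays, Twist cKO replicate 3 and Snail cKO replicate 3 (array set 1), and 115.4 to 125.4 on replicates 1 and 2 of both cKO groups (array set 2). Over the 14482 probes undetected on every array, the raw signals of 2 arrays of set 1 correlated with a median Spearman rho of 0.301 across probes, those of set 2 with 0.507, and those across sets with 0.194. The slide of each array is not given in the sources used here. All 3 KPC arrays lay in set 1, so every difference from KPC below was also computed with the array set as a block and within set 1, where 1 Twist cKO and 1 Snail cKO tumour remained. Of 110 single-gene differences from KPC, 38 shrank by more than 1.5 times or turned with the block, and 44 without KPC replicate 1 and Twist cKO replicate 2. The block is estimated only from replicates 1 and 2 against replicate 3 of each cKO group. It therefore also takes up what set single tumours apart, such as Twist cKO replicate 2 and Snail cKO replicate 2, and cannot tell this from an effect of the array set.

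**Figure D2:**
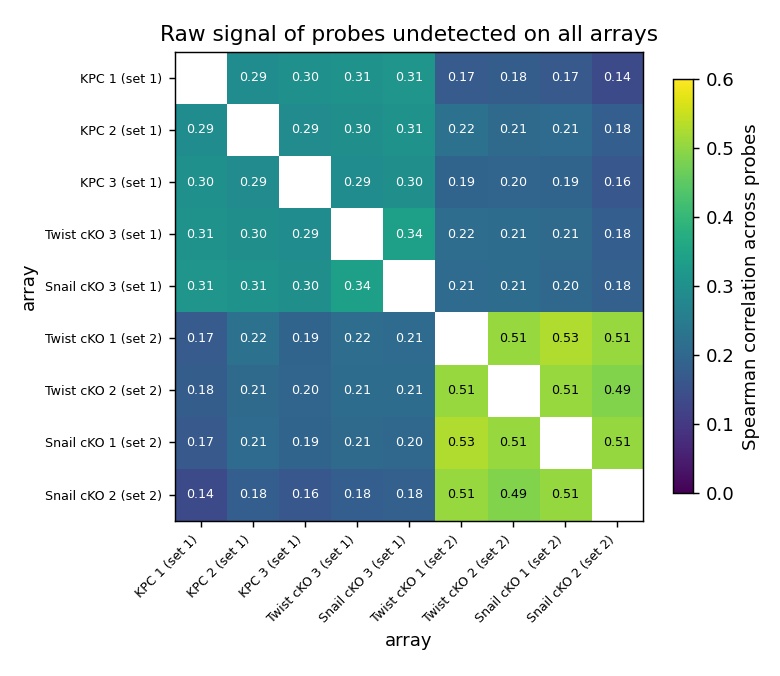
Spearman correlation, across the probes undetected on all 9 arrays, between the raw signals of each pair of arrays, named by group and replicate on both axes. Pairs within array set 2 reached 0.486 to 0.530, pairs within set 1 0.290 to 0.338, and pairs across sets 0.136 to 0.224.

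The targeted genes were read first. Twist1 averaged 7.97 ± 1.06 on the log2 scale in KPC tumours (SD, n = 3), 4.83 ± 0.35 in Twist cKO tumours and 6.96 ± 2.07 in Snail cKO tumours. In the Twist cKO group it was 4.60, 4.67 and 5.23 and was detected on 1 of the 3 arrays, while every KPC tumour lay at 7.25 or above. Twist1 was thus lower in Twist cKO than in KPC tumours by a log2 difference of -3.13 (SE 0.95), with an unadjusted p of 0.00997 and an adjusted p of 0.978 in limma. The exact two-sided permutation test gave p = 0.1, the smallest that 3 tumours against 3 allow. With the array set as a block the difference was -2.63, and within array set 1 it was -2.73. Snail cKO replicate 2, at 4.65, was the only tumour outside the Twist cKO group in which Twist1 was not detected, and it also had the lowest median of fibroblast and extracellular matrix genes (-1.52). Snai1 was detected in the Snail cKO tumours, at 7.06 ± 0.88 (SD, n = 3) against 7.42 ± 0.51 in KPC and 6.90 ± 1.10 in Twist cKO tumours. Its difference between Snail cKO and KPC was -0.36 (SE 0.63), with an exact permutation p of 0.6. With the array set as a block it turned to 0.17, and without Snail cKO replicate 2 to 0.13. A second Snai1 probe was undetected on all arrays. Where these probes lie relative to the deleted part of either gene is not given in the sources used here, so the probes check the labels only as far as these levels do, and the Snai1 probe separated no group.

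**Figure D3:**
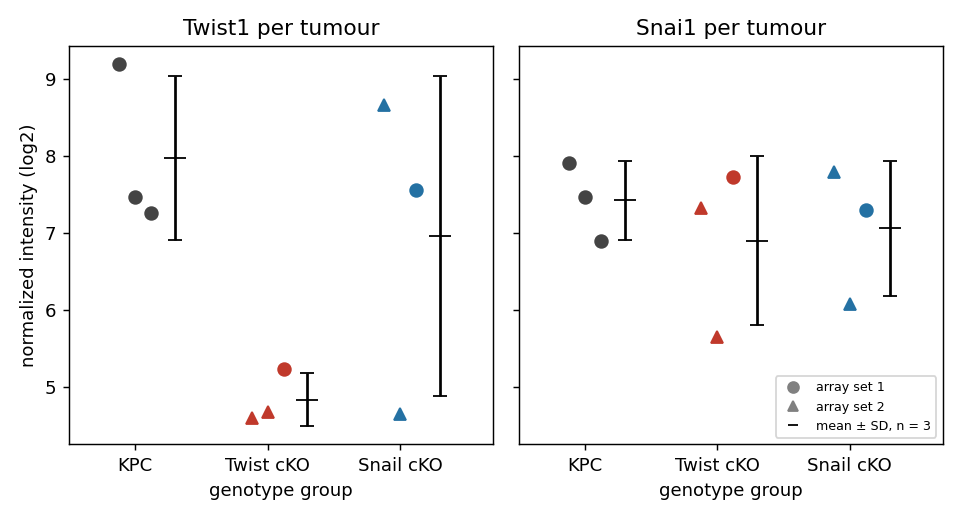
Normalized log2 intensity of Twist1 and Snai1 in each tumour (points, shaped by array set) with the mean and SD of each group (bars, n = 3). All 3 Twist cKO tumours lie at 5.23 or below for Twist1, and the groups overlap for Snai1.

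The comparison of Twist cKO with KPC tumours asks what differs in tumours labelled as lacking Twist. Smoc1, a secreted matricellular protein of the SPARC family, was higher in all 3 Twist cKO tumours, by 3.41 (SE 0.58) on the log2 scale. The histone genes H2ac19, H1f2 and H4c8 were higher by 1.82 (SE 0.35), 2.15 (SE 0.42) and 2.41 (SE 0.51). Slf1, a DNA repair factor that works with the SMC5/6 complex, was detected in the 3 Twist cKO tumours and in none of the others, which put it at least 2.14-fold above KPC. Lower values were seen for Soga3 (-3.47, SE 0.78), Atp6v0e2 (-2.05, SE 0.50), a subunit of the proton pump of acidic organelles, Snord123 (-1.56), a small nucleolar RNA, Adgra2 (-1.47), an adhesion receptor of vessels, and Snx16 (-1.05), a sorting protein of endosomes. None of these 10 genes, the 5 of smallest p in each direction, passed the test. Of the genes named in this comparison, Soga3, Foxc2, Fcer1g and Cd3d were above background on 1 of the 3 Twist cKO arrays and Atp6v0e2, Cftr, Gkn1, Gkn2, Cd22 and Lep on 2, and of the KPC arrays Cd3d, Cd22 and Fga on 1 and Cd79b on 2.

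The lists below are given by how many members had means on one side, and the fry test called 0 of them. Mesenchymal genes had lower means in Twist cKO tumours for 15 of 16 members (median -0.68), among them the matrix metalloproteinase genes Mmp3 (-1.93, SE 1.21) and Mmp14 (-1.03, SE 0.75) and the fibronectin receptor subunit Itga5 (-1.13, SE 0.77). Fibroblast and extracellular matrix genes were lower for 16 of 19 (median -0.45), with Fbln1 at -1.15, Fbln2 at -1.70 and the collagen gene Col3a1 at -1.31. Of the 12 EMT transcription factors 9 were lower (median -0.36), with Foxc2 at -1.51 (SE 0.51) and Zeb1 at -0.20 (SE 0.52). Twist cKO replicate 2 had the lowest mesenchymal and fibroblast medians of its group (-1.30 and -1.11), while replicate 3 stood at 0.73 and 0.81. Within array set 1, where Twist cKO is replicate 3 alone, Itga5, Mmp14, Col3a1 and Zeb1 turned to 0.36, 0.47, 0.26 and 0.14. Epithelial junction and keratin genes were lower for 15 of 21 (median -0.24), for instance the tight junction gene Tjp1 (-0.52), with the desmosome gene Pkp3 at 0.79 and at -0.26 without KPC replicate 1. Duct cell markers were lower for 7 of 8 (median -0.71) and mucinous and gastric metaplasia markers for 9 of 12 (median -0.93). Examples were Sox9 (-3.02), Cftr (-1.57), Gkn1 (-2.18) and Gkn2 (-2.28), which within array set 1 were at 0.077, 0.39, 0.76 and 1.43.

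Acinar cell markers were higher in Twist cKO tumours for 21 of 24 members (median 1.199), with the amylase gene Amy2a5 at 3.61 (SE 1.75), and endothelial markers for 13 of 15 (median 0.64), with Cldn5 at 1.71 and Pecam1 at 1.25. Markers of B and plasma cells were higher for 6 of 6 (median 1.82), of T cells for 3 of 5 (0.90) and of adipocytes for 5 of 5 (1.78). These values moved with Twist cKO replicate 2. Without it and KPC replicate 1, Cd79b and Cd22 of the B cell receptor complex went from 2.67 and 1.64 to -0.13 and -0.12, the T cell receptor gene Cd3d from 2.45 to -0.29 and the hormone gene Lep from 1.40 to -0.016. Of the adipocyte markers, Pparg was at 1.19. Macrophage and monocyte markers were lower for 11 of 16 (median -0.06), with the scavenger receptor Cd163 at -2.09 (SE 0.86) and -0.76 without those 2 tumours. The Fc receptor gene Fcer1g, at -4.55 (SE 1.46), was at 10.44 in Twist cKO replicate 1 and at 4.46 and 4.52 in replicates 2 and 3. Hepatocyte markers were higher for 6 of 7 (median 0.61), with the fibrinogen gene Fga at 1.75, neutrophil markers for 6 of 9 (0.25), erythroid genes for 3 of 4 (0.70), smooth muscle markers for 3 of 5 (0.61), interferon response genes for 9 of 12 (0.36), skeletal muscle markers for 2 of 3 (0.17) and islet markers for 3 of 11 (-0.09).

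Proliferation genes were lower in Twist cKO tumours for 18 of 20 members (median -0.20), with the replication helicase genes Mcm2 and Mcm6 at -0.59 (SE 0.32) and -0.49 (SE 0.26). The lower means followed KPC replicate 1, whose list median was 0.87. It was -0.56 and -0.31 in the other KPC tumours and -0.44, -0.23 and -0.10 in Twist cKO replicates 1, 2 and 3. Nucleoside transport and gemcitabine metabolism, which handles the drug most used against this cancer, was lower for 12 of 21 (median -0.13), with the kinase gene Nme1 at -0.52, the deaminase gene Dctd at -1.06 and the transporter gene Slc29a1 at -0.027 (SE 0.43, and 0.016 with cyclic loess). TGF-beta pathway genes were lower for 9 of 14 (median -0.13), with Pmepa1 at -1.65 (0.41 within array set 1) and the differentiation inhibitor Id2 at 0.90 (SE 0.31). Hypoxia and glycolysis genes were lower for 7 of 13 (median -0.07) and handling stress genes for 7 of 10 (median -0.26), with the heat shock gene Hspa1a at 1.32 (SE 0.44) and Egr1 at -0.73.

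Many of these values changed without 1 tumour or with the array set as a block, 2 fits that overlap because Twist cKO replicate 2 lay in set 2. Without Twist cKO replicate 2, Gkn1 was at -0.062, Gkn2 at -0.15, Cftr at -0.37, Sox9 at -1.10, Mmp14 at -0.11, Itga5 at -0.43, Fbln2 at -0.18, Col3a1 at -0.15, Pmepa1 at -0.64, Pecam1 at 0.58 and Dctd at -0.67. Without KPC replicate 1, Mmp3 was at -0.91, Foxc2 at -0.99, Cldn5 at 0.93, Pparg at 0.25, Cd163 at -1.09 and Mcm6 at -0.31, while Tjp1 was at -0.076 without KPC replicate 3 and Fga at 1.06 without Twist cKO replicate 3. The array set as a block put Cftr at 0.14, Gkn1 at -0.37, Gkn2 at 0.050, Sox9 at -1.01, Mmp3 at -0.66, Mmp14 at -0.013, Itga5 at -0.36, Fbln1 at -0.31, Fbln2 at -0.63, Col3a1 at -0.18, Pmepa1 at -0.14, Cldn5 at 0.70, Pecam1 at 0.57, Cd163 at -1.35, Tjp1 at -0.27, Hspa1a at 0.82, Cd3d at 0.70, Cd22 and Cd79b at 0.55 each and Lep at 0.83.

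In this comparison limma called 0 of 11524 genes (smallest adjusted p 0.978), and 407 had an unadjusted p under 0.05 where chance alone gives 576.2. That count ran from 292 without Twist cKO replicate 1 to 929 without replicate 3, so whether it lies below chance rests on 1 tumour. The 3 Twist cKO tumours lay above all KPC tumours for 345 genes and below them for 583, or 8.05% of genes where 10% is the share chance gives. No list member passed over all genes (0) or adjusted over the list alone (0, smallest adjusted p 0.101). The fry test called 0 of 23 lists (smallest adjusted p 0.895, and 0 with an unadjusted p under 0.05), its mixed form 0, and camera with a preset correlation 6, namely the endothelial (adjusted p 0.000264), acinar, B and plasma cell, adipocyte and hepatocyte lists upward and the mesenchymal list downward (0.0426). For each of these 6, camera gave an adjusted p = 0.913 with an estimated correlation. Without Twist cKO replicate 1, 3 genes passed, Fcer1g, Gdpd3 and Thumpd1, of which the last 2 were named after their values were seen. Blocking on the array set left 0 genes past the threshold and 165 had an unadjusted p under 0.05, and within set 1 these were 0 and 152.

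The comparison of Snail cKO with KPC tumours asks the same of tumours labelled as lacking Snail, in which Snai1 was still detected. The transcription factor gene Tfap2a was higher in all 3 Snail cKO tumours. Its probe was not above background in any KPC tumour, which put it at least 2.60-fold higher, although another of its probes was detected in 1 of them. Sys1, a Golgi trafficking protein, was higher by 1.64 (SE 0.25) on the log2 scale, the class II antigen presentation gene H2-Aa by 3.05 (SE 0.61), the lipid transporter gene Mfsd2a by 1.40 and the RNA polymerase I subunit gene Polr1b by 2.56. Lower values were seen for the calcium-binding protein sorcin (Sri, -1.61, SE 0.25), the oxysterol hydroxylase Cyp7b1 (-1.78), the glycogen phosphorylase Pygb (-1.75), the S-adenosylhomocysteine hydrolase Ahcy (-2.03) and Fap (-1.82, SE 0.39), a serine protease of activated fibroblasts. Other probes gave -1.29, -0.92 and -0.12 for Sri and -1.27 for Ahcy. None of the 10 passed over all genes. In this comparison Foxc2 and Twist2 were above background on 1 of the 3 Snail cKO arrays and Fap, Prss3 and Hbb-b2 on 2, and of the KPC arrays Prss3, Hbb-b2 and Myh11 on 1 and Polr1b, Muc5ac, Agr2 and Tjp3 on 2.

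All 16 macrophage and monocyte markers had lower means in Snail cKO than in KPC tumours (median -0.998), with Cd163 at -2.33 (SE 0.86) and the mannose receptor Mrc1 at -0.99 (SE 0.44). KPC replicate 1 had the highest macrophage median of all 9 tumours (1.86), and without it and Twist cKO replicate 2 Cd163 was at -1.33. Fibroblast and extracellular matrix genes were lower for 15 of 19 (median -0.38), with Col5a2 at -1.51 and Col3a1 at -1.12, or -0.41 and 0.012 with the array set as a block. Mesenchymal genes were lower for 13 of 16 (median -0.38), with Mmp3 at -1.49 and the receptor kinase gene Axl at -0.55, or -0.22 and 0.10 with the block. Snail cKO replicate 2 carried both lists, with fibroblast and mesenchymal medians of -1.52 and -1.11. They were 0.18 and 0.81 in replicate 1 and 0.48 and 0.28 in replicate 3. EMT transcription factors were lower for 9 of 12 (median -0.30), with Foxc2 at -1.51 (SE 0.51), Twist2 at -1.15 and Zeb1 at -0.14, which turned to 0.18 without KPC replicate 1. TGF-beta pathway genes were lower for 11 of 14 (median -0.28), and Ltbp2, which was detected in 3 KPC and 0 Snail cKO tumours, was at least 1.14-fold lower.

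All 24 acinar cell markers had higher means in Snail cKO tumours (median 1.54), with the elastase gene Cela1 at 1.68 (SE 0.78) and the trypsinogen gene Prss3 at 1.83 (SE 1.10), and Snail cKO replicate 3 held the highest acinar median of the 9 tumours. Without it Prss3 was at 0.47. Mucinous markers were higher for 12 of 12 (median 1.09), with the mucin gene Muc5ac at 2.88 (SE 1.95) and Agr2 at 0.77 (SE 0.38). Duct cell markers were higher for 7 of 8 (median 1.08), with the water channel gene Aqp5 at 2.63 (SE 1.15) and the keratin gene Krt19 at 1.51 (SE 1.71), and epithelial junction and keratin genes for 17 of 21 (median 0.34), with Tjp3 at 1.39. Hypoxia and glycolysis genes were higher for 12 of 13 (median 0.44), with Pdk1 at 1.34 (SE 0.56, and 0.51 with the array set as a block) and Ndrg1 at 1.22, and erythroid genes for 4 of 4 (median 1.57), with the globin genes Hbb-b2 at 1.77 and Hba-a1 at 1.81. Snail cKO replicate 1 had the highest median of both lists (1.01 and 2.60). Nucleoside metabolism was higher for 16 of 21 members (median 0.21), with the cytidine deaminase gene Cda at 2.07 (SE 0.87), Cmpk1 at 0.48 and Slc29a1 at 0.072 (SE 0.43, and -0.058 with median scaling), and proliferation genes for 15 of 20 (median 0.25), with Cdc20 at 1.19.

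The mucinous, duct and epithelial medians were -2.52, -2.40 and -2.19 in KPC replicate 1 and between 0.84 and 1.37 in the other KPC tumours. Without KPC replicate 1, Krt19 was at 0.55, Tjp3 at 0.50, Ndrg1 at 0.62, Twist2 at -0.16, Foxc2 at -0.99, Mmp3 at -0.47, Mrc1 at -0.61 and Hspa1a at 0.76 (0.64 with the block). Without Snail cKO replicate 2, Muc5ac was at 1.16, Col5a2 at -0.80, Col3a1 at -0.58, Axl at -0.11 and Dusp1 at -0.65. Agr2 was at 0.42 and Cmpk1 at 0.28 without Snail cKO replicate 3, Hbb-b2 at 0.99 and Hba-a1 at 0.94 without Snail cKO replicate 1, and Cdc20 at 0.65 without KPC replicate 2.

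Endothelial markers were higher for 13 of 15 members (median 0.28), B and plasma cell markers for 6 of 6 (0.71), T cell markers for 4 of 5 (0.07), adipocyte markers for 4 of 5 (0.57), hepatocyte markers for 5 of 7 (0.66), interferon response genes for 8 of 12 (0.39), and smooth muscle markers for 3 of 5 (1.84), with Myh11 at 2.32 (SE 1.11). Snail cKO replicate 3 carried the smooth muscle list, with a median of 3.23 against 0.09 and -0.35 in replicates 1 and 2, and Myh11 was at 0.90 without it. In Snail cKO replicates 1, 2 and 3, the B and plasma cell median was -1.14, 1.56 and -0.96 and the adipocyte median -1.48, 1.36 and -0.04, so replicate 2 carried both. Handling stress genes were lower for 7 of 10 (-0.11), with Dusp1 at -0.98 and Hspa1a at 1.15, and islet markers for 7 of 11 (-0.19). The islet list's mean was -0.13 while fry put it upward, the neutrophil list (5 of 9 higher, Csf3r at -0.84) had a median of 0.20, a mean of 0.008 and a downward test, and the 3 skeletal muscle genes tested had a median of 0.18 and a mean of -0.11.

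The limma test called 0 of 11524 genes between Snail cKO and KPC (smallest adjusted p 0.553), with 310 at an unadjusted p under 0.05 where chance gives 576.2. With 1 tumour left out there were 203 (without Snail cKO replicate 2) to 419 (without Twist cKO replicate 2), and 582 without KPC replicate 1 and Twist cKO replicate 2. Groups were apart for 328 genes higher and 672 lower in Snail cKO, or 8.68% against 10% by chance. No list member passed over all genes (0), and adjusted over the list alone 1 did, Fap (adjusted p 0.0254). The fry test called 0 of 23 lists (smallest adjusted p 0.919, and 0 at an unadjusted p under 0.05), its mixed form 0, and camera with a preset correlation 6, the acinar (8.01e-06), erythroid, hypoxia, mucinous and duct lists upward and the macrophage list downward (5.36e-05). With an estimated correlation camera called 0, with an adjusted p = 0.574 for the erythroid and hypoxia lists, 0.602 for the macrophage list and 0.760 for the other 3. With a block for the array set 0 genes passed and 215 had an unadjusted p under 0.05, and within set 1 these were 0 and 297.

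The comparison of Snail cKO with Twist cKO tumours sets the 2 labels against each other, with Snai1 still detected in every Snail cKO tumour, and it is the only one in which both groups had arrays in both sets. Duct cell markers had higher means in Snail cKO tumours for 8 of 8 members (median 2.03), with Aqp5 at 3.40 (SE 1.15), the chloride channel gene Cftr at 2.68 (SE 1.43) and Krt19 at 2.37 (SE 1.71), and mucinous markers for 12 of 12 (median 2.64), with Muc6 at 2.63 and Agr2 at 0.93. Twist cKO replicate 2 had the lowest median of both lists, and without it and KPC replicate 1 Aqp5 was at 2.06, Cftr at 1.48 and Krt19 at 0.15. Proliferation genes were higher for 20 of 20 (median 0.43), with the mitotic genes Cdc20 at 1.23 (SE 0.56) and Aurkb at 1.00 (SE 0.49), and hypoxia and glycolysis genes for 13 of 13 (median 0.55), with the carbonic anhydrase gene Car9 at 2.15 (SE 1.13) and the collagen hydroxylase gene P4ha2 at 1.31, or 1.06 and 0.37 without Twist cKO replicate 2. Nucleoside metabolism was higher for 14 of 21 (median 0.11), with Nme1 at 0.53 (SE 0.21), Dctd at 1.29 (SE 0.55), Cda at 1.70 and Slc29a1 at 0.10, the last turning to -0.037 with median scaling. Cda was at 0.69 without Twist cKO replicate 2, Muc6 at 1.19 and Agr2 at 0.58 without Snail cKO replicate 3.

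The 5 genes of smallest p that were higher in Snail cKO were Sys1 (1.66, SE 0.25), Mfsd2a (2.02, SE 0.31), Ppp1r3b (1.75, SE 0.29), which targets a phosphatase to glycogen, Tfap2a (1.67) and the neuronal pentraxin gene Nptx1 (2.49). Those lower were Sri (-1.93, SE 0.25, with other probes at -1.96, -1.98 and -0.20), Serinc3 (-2.07), Pygb (-1.59), and Rarres1 and Slf1. The last 2 were undetected in every Snail cKO tumour, Rarres1 at least 5.05-fold and Slf1 at least 1.99-fold lower there. Of the genes named in this comparison, Tfap2a, Nptx1, Muc6, Agr2 and Fcer1g were above background on 1 of the 3 Twist cKO arrays and Aqp5, Cftr, Krt19 and Cda on 2, and Muc6, Fap and Hbb-b2 on 2 of the 3 Snail cKO arrays. Within the 2 array sets, Sys1 differed by 1.07 in set 1 and 1.95 in set 2, and Sri by -2.21 and -1.78. Other genes differed mostly in set 2, Cdc20 by 0.26 in set 1 and 1.71 in set 2, Aurkb by 0.26 and 1.37, Dctd by 0.33 and 1.77, Krt19 by 0.82 and 3.14 and P4ha2 by 0.83 and 1.55, and Muc6 and Agr2 more in set 1, by 4.62 and 1.56 against 1.64 and 0.61.

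Among the other lists, endothelial markers were lower in Snail cKO tumours for 13 of 15 (median -0.37), with Pecam1 at -1.05, macrophage markers for 13 of 16 (-0.61), with Fcer1g at 3.60, B and plasma cell markers for 6 of 6 (-1.23), adipocyte markers for 5 of 5 (-1.25), T cell markers for 3 of 5 (-0.88), neutrophil markers for 6 of 9 (-0.54) and TGF-beta pathway genes for 8 of 14 (-0.07). The B and plasma cell, adipocyte and T cell values here were set by Twist cKO replicate 2 (4.82, 5.40 and 2.59), without which Pecam1 was at -0.38 and Cela1, named below, at 1.80. Fibroblast genes were split, 10 of 19 lower (-0.04), with Fap at -1.46 (SE 0.39) and Fbln1 at 1.18. Higher were epithelial genes for 15 of 21 (0.61), mesenchymal genes for 11 of 16 (0.50), EMT transcription factors for 8 of 12 (0.04), acinar markers for 16 of 24 (0.22), with Cela1 at 2.79, erythroid genes for 4 of 4 (0.62), with Hbb-b2 at least 3.32-fold higher, smooth muscle markers for 5 of 5 (0.60) and handling stress genes for 6 of 10 (0.16). The erythroid list median was 2.60, -0.80 and 0.66 in Snail cKO replicates 1, 2 and 3, so replicate 1 stood apart. Islet markers had a median of 0.22 and a mean of -0.009, interferon response genes a median of 0.15 and a mean of -0.06, both with an upward test. Hepatocyte markers had a median of 0.15 and a downward test, with Fga at least 2.88-fold lower. The hepatocyte list median was 0.64, -1.20 and 1.59 in Twist cKO replicates 1, 2 and 3.

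Between the cKO groups limma called 0 of 11524 genes (smallest adjusted p 0.433), with 436 at an unadjusted p under 0.05 where chance gives 576.2, or from 348 without Snail cKO replicate 2 to 839 without Twist cKO replicate 3. Groups were apart for 490 genes higher and 458 lower in Snail cKO, or 8.23% against 10% by chance. No list member passed over all genes (0), and adjusted over the list alone 1 did, Id2 of the TGF-beta list (-1.28, SE 0.31, adjusted p 0.0420). The fry test called 0 of 23 lists and its mixed form 0. Its smallest adjusted p, 0.612, was that of nucleoside metabolism, the 1 list at an unadjusted p under 0.05. Camera with a preset correlation called 4, the hypoxia, mucinous and proliferation lists (each with adjusted p 0.00111) and the duct list (0.00296), all upward, and with an estimated correlation 0, each of these at adjusted p = 0.865 with an estimated correlation. Without Twist cKO replicate 1 limma called 1 gene, Thumpd1. Fitted with the array set as a block, 0 genes passed and 426 had an unadjusted p under 0.05, and within sets 1 and 2 0 and 0 passed, with 242 and 449.

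Taking both cKO groups against KPC averages the 2 differences from KPC, so a large difference in 1 group can carry the value alone. Smoc1 (2.36, SE 0.51), H2ac19 (1.31), H4c8 (1.76) and the adhesion gene Flrt3 (1.89) were higher, as was Tfap2a, which was above background in 0 KPC, 1 Twist cKO and 3 Snail cKO tumours and so rested on Snail cKO, and Cyp7b1 (-1.49, SE 0.29), Atp6v0e2 (-1.92), Adgra2 (-1.36), Snx16 (-0.93) and Ccdc91 (-1.13) lower, none passing the test. Smoc1, H2ac19 and H4c8 differed from KPC by 3.41, 1.82 and 2.41 in Twist cKO and by 1.31, 0.79 and 1.10 in Snail cKO. Acinar markers were higher for 24 of 24 members (median 1.32), with Amy2a5 at 2.64 (SE 1.52) and Zg16 at 2.82 (SE 1.86), and endothelial markers for 15 of 15 (0.47), with Cldn5 at 1.23 (SE 0.73), or 0.22 with the array set as a block and 0.098 without KPC replicate 1 and Twist cKO replicate 2. All 16 macrophage markers were lower (-0.54), with Cd163 at -2.21 (SE 0.75, and -1.04 without KPC replicate 1 and Twist cKO replicate 2) and Mrc1 at -0.85. EMT transcription factors were lower for 10 of 12 (-0.26), with Foxc2 at -1.51, mesenchymal genes for 14 of 16 (-0.53), with Mmp3 at -1.71 (-0.44 with the block), and fibroblast genes for 16 of 19 (-0.48), with Fap at -1.09 (SE 0.34). Hypoxia genes were higher for 11 of 13 (0.25), with Pdk1 at 1.04 (0.21 with the block), erythroid genes for 4 of 4 (0.99), hepatocyte markers for 6 of 7 (0.73), B and plasma cell markers for 6 of 6 (1.27), and nucleoside metabolism for 13 of 21 (0.06), with Cda at 1.22. Hspa1a was at 1.24 (SE 0.38) and Myh11 at 2.02 (SE 0.96). For Hspa1a, the difference of each cKO group from KPC shrank with the array set as a block, as given above. Foxc2 and Zg16 were above background on 1 of the 3 Snail cKO arrays and Atp6v0e2 and Fap on 2, Foxc2 on 1 of the 3 Twist cKO arrays and Atp6v0e2 and Cda on 2, and Zg16 and Myh11 on 1 of the 3 KPC arrays. The B and plasma cell median was 4.82 in Twist cKO replicate 2 and 1.56 in Snail cKO replicate 2, and between -1.26 and -0.76 in the other 4 cKO tumours. Fibroblast and mesenchymal medians were -1.11 and -1.30 in Twist cKO replicate 2 and -1.52 and -1.11 in Snail cKO replicate 2. In the other 4 cKO tumours they lay between 0.18 and 0.81 and between -0.17 and 0.81. KPC tumours had -0.08 to 0.77 and -0.18 to 0.875. Without Snail cKO replicate 3 Zg16 was at 1.30 and Myh11 at 1.31, and without KPC replicate 1 Amy2a5 was at 1.54, Mmp3 at -0.69, Mrc1 at -0.46 and Foxc2 at -0.99. The proliferation list had a median of 0.02, a mean of 0.008 and a downward test.

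The limma test called 0 of 11524 genes for both groups against KPC (smallest adjusted p 0.999), with 331 at an unadjusted p under 0.05 where chance gives 576.2. Leaving out 1 tumour gave from 253 (Snail cKO replicate 2) to 554 (Twist cKO replicate 3), and leaving out KPC replicate 1 and Twist cKO replicate 2 gave 515. All 6 cKO tumours lay above the KPC tumours for 70 genes and below for 152, or 1.93% against 2.38% by chance. No list member passed over all genes (0) or adjusted over the list alone (0, smallest adjusted p 0.0997). The fry test called 0 of 23 lists (smallest adjusted p 0.918, and 0 at an unadjusted p under 0.05), its mixed form 0, and camera with a preset correlation 7, the acinar, endothelial, erythroid, hepatocyte, B and plasma cell and hypoxia lists upward and the macrophage list downward. Each of these 7 had an adjusted p = 0.729 with an estimated correlation. In the fit blocked by array set 0 genes passed and 157 had an unadjusted p under 0.05, and within set 1 these were 0 and 252.

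Across genes, the log2 differences of Twist cKO and of Snail cKO from KPC correlated with r = 0.426 over 11524 genes, which are not independent replicates. Both share the 3 KPC tumours, and 200 simulated sets of unchanged groups sharing 3 controls gave a mean r of 0.478, with 95% of them between -0.242 and 0.904. The covariance was 0.129 against a simulated 0.214, a difference of -0.0854. Of the genes with an unadjusted p under 0.05 in both comparisons, 75 of 78 went the same way. In 100 simulated sets of unchanged groups sharing 3 controls, a mean of 116 genes did so (median 34.5, 95% of sets between 0 and 610), so the observed count lay within what shared controls give. The 3 controls could not be split into parts of 2 each.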

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

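The fits with the array set as a block, within an array set, and without KPC replicate 1 and Twist cKO replicate 2 were chosen after seeing the data. Over all alternatives, the single-gene values kept their direction and their side of the threshold in 3221 of 3289 cases, reversed in 67 and became stronger in 1, the counts of genes stayed the same in 88 of 92 cases, the counts of lists in 96 of 100, and the correlation of the 2 effects stayed within its bounds in 15 of 22. As no single-gene value passed the test in the first place, keeping its side says little about stability. The counts of genes and lists were 0 in the reported fit of every comparison, so their staying the same says as little. Signal over background limits Twist1, which lay near background in 4 of the 9 tumours. Its difference between Twist cKO and KPC ranged from -1.62 without background correction to -3.52 with the title series as a block. The array slide as a block was not run, since the slide is not given in the sources used here, Twist1 had no value under a detection p-value under 0.01 on all 9 arrays, and array set 2 alone holds no KPC tumour. No paired analysis was possible because the groups share no mouse numbers. Where a change below has no stated cause, the cause was not tested.

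With every probe tested, 1 gene (Glrx) passed for Twist cKO against KPC and 1 (Glrx again) for both groups against KPC, with smallest adjusted p of 0.0339 and 0.0230 in limma. Leaving out each replicate gave 0 to 3 genes for Twist cKO against KPC and 0 to 1 for Snail cKO against Twist cKO, the highest in both without Twist cKO replicate 1, and 0 to 0 for the other comparisons. For Twist cKO against KPC, Fcer1g then stood at -6.53. Camera with the preset correlation called 6, 6, 4 and 7 lists for Twist cKO against KPC, Snail cKO against KPC, Snail cKO against Twist cKO and both groups against KPC, where fry and camera with an estimated correlation called 0. The correlation of the 2 effects, 0.426, became 0.563 with the title series as a block and 0.555 with the array set as a block, and 0.297 (without Twist cKO replicate 1) to 0.565 (without KPC replicate 2 or 3) when a replicate was left out. At an unadjusted p under 0.05, array weights gave 654, 778 and 878 genes for Twist cKO, Snail cKO and both against KPC, where the reported fit gave 407, 310 and 331. The title series as a block gave 163 for Snail cKO against Twist cKO (436 as reported) and 560 for both groups against KPC.

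The array set as a block reversed these differences. Snai1 went to 0.17 for Snail cKO, 0.013 for Twist cKO and 0.093 for both against KPC. In Twist cKO against KPC, Cftr went to 0.14, Gkn2 to 0.05 and Slc29a1 to 0.24, and in Snail cKO against KPC Axl to 0.10 and Col3a1 to 0.012. Within array set 1, with 1 Twist cKO and 1 Snail cKO tumour assumed to vary like the KPC tumours, Snai1 was at 0.31 for Twist cKO against KPC, -0.43 for Snail cKO against Twist cKO and 0.093 for both against KPC. There Twist cKO against KPC reversed for Cd22 (-0.15), Cd3d (-0.10), Cd79b (-0.22), Cftr (0.39), Col3a1 (0.26), Gkn1 (0.76), Gkn2 (1.43), Itga5 (0.36), Mmp14 (0.47), Pmepa1 (0.41), Slc29a1 (0.83), Sox9 (0.077) and Zeb1 (0.14), while Slc29a1 was at -0.25 for Snail cKO against KPC and -1.09 for Snail cKO against Twist cKO. Without KPC replicate 1 and Twist cKO replicate 2, Twist cKO against KPC reversed for Cd22 (-0.12), Cd3d (-0.29), Cd79b (-0.13), Lep (-0.016), Pkp3 (-0.27) and Snai1 (0.35). In the same fit Snai1 was at -0.46 for Snail cKO against Twist cKO and 0.12 for both against KPC, and Slc29a1 at -0.028 and Zeb1 at 0.18 for Snail cKO against KPC.

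The deposited processed values turned Slc29a1 (0.26) and Zeb1 (0.084) in Twist cKO against KPC and Zeb1 (0.16) in Snail cKO against KPC. Cyclic loess turned Slc29a1 in Twist cKO against KPC (0.016), and median scaling turned it in Snail cKO against KPC (-0.058) and against Twist cKO (-0.037). Array weights gave Slc29a1 -0.12 and -0.025 in the same 2 comparisons and Snai1 -0.078 for Snail cKO against Twist cKO, and the title series as a block gave Slc29a1 -0.36 and -0.30. Leaving out each replicate gave, for Twist cKO against KPC, Cd22 -0.004 to 2.54, Cd3d -0.17 to 3.80, Lep -0.066 to 2.17, Pkp3 -0.26 to 1.46, Slc29a1 -0.46 to 0.36, Snai1 -0.93 to 0.10 and Zeb1 -0.59 to 0.36. For Snail cKO against KPC the ranges were -0.20 to 0.24 for Slc29a1, -0.73 to 0.13 for Snai1, -1.86 to 0.15 for Twist1 and -0.42 to 0.18 for Zeb1. For Snail cKO against Twist cKO they were -0.29 to 0.53 for Slc29a1 and -0.46 to 0.65 for Snai1.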

Other observations

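The tests of the 3 patterns below, and the histone and lymph node gene sets, were chosen after the results were seen, while the splits of the tumours were planned. Of the 5 genes of smallest p that were higher in Twist cKO than in KPC tumours, 3 were histone genes of the replication-dependent clusters, the group that supplies new chromatin in S phase, and the set was drawn up after that was seen. Of 46 such genes measured, 44 had higher means in Twist cKO than in KPC tumours (median 0.68 on the log2 scale), 17 with an unadjusted p under 0.05 (37.0%, against 3.53% of all genes), and 9 had all 3 Twist cKO tumours above all 3 KPC tumours. With the array set as a block 41 were higher (median 0.86) and 16 had an unadjusted p under 0.05. In Snail cKO tumours 33 were higher (median 0.42), 0 with an unadjusted p under 0.05. Per tumour, the median deviation of these genes was 0.05, -0.71 and -0.38 in KPC, 0.46, 0.15 and 0.84 in Twist cKO, and 0.39, -0.47 and -0.16 in Snail cKO. Proliferation genes had lower means in Twist cKO tumours for 18 of 20, but this followed KPC replicate 1, with a list median of 0.87. The other KPC medians were -0.56 and -0.31, against -0.44, -0.23 and -0.10 in Twist cKO replicates 1, 2 and 3. Many histone genes are near-identical copies, so their probes are not independent measurements. No test of the set against other genes was run, and no explanation was tested.

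The probes of some genes were bright in some tumours of a group and near background in others, which does not show that the gene itself was absent. Those named here were chosen after their values were seen. Thumpd1, an RNA-binding protein gene, was at 10.02 in Twist cKO replicate 1, at 4.49 and 4.31 in replicates 2 and 3, and at 8.76 to 10.03 in the KPC tumours. Fcer1g was likewise at 4.46 and 4.52 in Twist cKO replicates 2 and 3, although the median of the macrophage list was 0.66 and -0.05 there and the KPC tumours stood at 9.69 to 12.20. The interferon response list was highest in Twist cKO replicate 2 (1.37), and the neutrophil list in Twist cKO replicate 1 (1.66).

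Twist cKO replicate 2 correlated with no other array above 0.829, while each of the other arrays reached at least 0.914 with another one. Twist cKO replicate 2 detected 18864 probes, against 16707 on Snail cKO replicate 2 and 19152 to 19606 on the other arrays. It lay within the range of the others only through that low array, and probe counts do not measure RNA quality. Poor RNA therefore stays open. A failed array is argued against as the whole cause, since it would not raise whole lists of cell type markers. Over all members on the array, the B and plasma cell, T cell and adipocyte lists stood at 4.28, 2.59 and 2.74 in Twist cKO replicate 2. On the other arrays they reached at most 0.707, -0.035 and 0.215. A turn of the tumour cells to a mesenchymal state cannot be judged from these values. The mesenchymal median (-1.30 over the genes tested, -0.81 over all members on the array) covers all cells of the piece, and the fibroblast median was low too (-1.11). A candidate explanation is lymph node and fat tissue in the piece, with the B and plasma cell list, over all its members on the array, at 4.28, the T cell list at 2.59 and the adipocyte list at 2.74, each above all of 10000 random lists of matched expression. Random genes need not move together as markers of 1 cell type do, so exceeding them says little. The endothelial (0.92) and interferon response (1.19) lists also lay above all 10000. In Twist cKO replicate 2, Cd79b was at 12.86, the lymph node chemokine gene Ccl21a at 14.12 and the fat hormone gene Adipoq at 12.96. A lymph node list written afterwards stood at 4.07 there. On the other arrays Cd79b reached 9.25 and Adipoq 7.76, both in Snail cKO replicate 2, and Ccl21a reached 10.64 in KPC replicate 2. Which tissue was sampled is not given in the sources used here, and no biological explanation tied to the genotype was tested.

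Twist1 was near background in the 3 Twist cKO tumours and in Snail cKO replicate 2. Fibroblasts express Twist1, yet a shortage of them is argued against in Twist cKO replicates 1 and 3, whose lower fibroblast median of 0.28 lay above the lowest KPC value of -0.08. For Twist cKO replicate 3 the array set is argued against, since this tumour lay in set 1 with the KPC tumours and 2.01 below the lowest of them (-2.01). For replicates 1 and 2, in set 2 with no KPC tumour, it stays open, as Twist1 in the 2 Snail cKO tumours of that set was at 8.66 in one and 2.59 below the lowest KPC value (-2.59) in the other. In Twist cKO replicate 2 a shortage of fibroblasts stays open, with a fibroblast median of -1.11 and, in Snail cKO replicate 2, -1.52 beside a Twist1 of 4.65. The epithelial median of Twist cKO replicate 2 was low too (-2.16), so its Twist1 says little about epithelial tumour cells. Deletion of Twist1, the difference the labels name, goes with the order of the groups, as all 3 Twist cKO tumours lay below all 3 KPC tumours (unadjusted limma p 0.00997 for a gene named in advance, 0.978 adjusted over all genes). It stays a hypothesis, since Snail cKO replicate 2 came to the same level without that label. A deletion that spared fibroblasts would also leave their Twist1. Yet Twist cKO replicates 1 and 3 were at 4.60 and 5.23 beside fibroblast medians of 0.28 and 0.81. KPC replicate 1, low in epithelial genes (-2.19), had the highest Twist1 (9.19). Which cells lacked Twist1 cannot be told from whole tumour pieces.

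Genes near Snai1 on its chromosome were over-represented among those of small p in Snail cKO against KPC. With up to 200 genes on each side, fewer where the chromosome ended, 17 of 278 measured genes (6.12%) had an unadjusted p under 0.05, against 2.61% elsewhere. That share was above 97.47% of equally long runs of genes. Among the 17 were Sys1, Pygb, Ahcy, Serinc3 and Flrt3. Flrt3 lay at the window's edge and was also higher than KPC in Twist cKO tumours (1.69, against 2.09 in Snail cKO). Others that moved alike there included Kif3b (1.409 against 1.502), Zfp217 (-0.686 against -0.691), Tti1 (-0.898 against -1.373) and Slc9a8 (0.728 against 1.085). Sys1, Pigt, Rbm12 and Serinc3 went the opposite way there. Only Zfp217 and Fam217b of the 17 lay on the side of Snai1 that the chromosome's end cut short. With 100 genes on each side the share was 5.62%, so it was no higher closer to Snai1. Of the 20 genes of smallest p, 7 lay on that chromosome, which holds 7.91% of the genes placed. The array set is argued against as the whole cause by the share with the array set as a block, above 99.19% of runs, and in Snail cKO against Twist cKO, where each group had 1 array in set 1 and 2 in set 2, above 98.54%. With the block, the share in Snail cKO against Twist cKO was above 94.62%. With 100 genes on each side, the share was above 86.05% for Snail cKO against KPC with the block. For Snail cKO against Twist cKO without it, the share was above 89.53%. DNA of another mouse strain, carried along with a targeted Snai1 allele, may account for it but stays open, since the share with 100 genes on each side was above 94.75% of runs and runs overlap. The same neighbourhood stood at 63.34% for Twist cKO against KPC, Twist1's own at 35.13% for Twist cKO against KPC, and the strains of the mice are not given in the sources used here.

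For the comparisons of 3 tumours with 3, the 10 splits of 6 tumours are too few for a share under 0.05. The real value and the highest of the other splits were 0 and 0 genes for Twist cKO against KPC (407 and 1042 at an unadjusted p under 0.05), 0 and 3 for Snail cKO against KPC (310 and 790), and 0 and 0 for Snail cKO against Twist cKO (436, with more in the highest of the others), and 0 and 0 lists in each. For both groups against KPC, the real 0 genes and 0 lists are reached by all of the 100 splits drawn, the real one included, whatever the data, so these counts decide nothing. By the count at an unadjusted p under 0.05, read afterwards, chance cannot be excluded for the genes, since 67 of 97 other splits gave at least the real 331. The splits part the tumours into 3 groups of 3, so these 97 hold 55 different sets of 3 against 6, and the remaining 3 set the KPC tumours against the others. The highest of the others called 170 genes when KPC replicate 1, Twist cKO replicate 2 and Snail cKO replicate 1 stood together, and the highest number of lists was 2. A split with so many genes points to a structure among the tumours, whose cause was not tested. Those 3 tumours, in the order named, had the lowest duct (-2.40, -3.95 and 0.14) and mucinous medians (-2.52, -4.57 and -0.10). They were also lowest in epithelial genes (-2.19, -2.16 and -0.235), with Snail cKO replicate 2 close at -0.14. The 2 tumours lowest in epithelial genes are also joined in 2 other splits, which called 0 genes, with 1171 and 1104 at an unadjusted p under 0.05.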
